A study of Homo sapiens with 18 samples.

How the data were processed

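RNA was measured by sequencing of poly(A)-selected libraries from LU99, an established human non-small cell lung cancer cell line. Per the labels' protocols, cells were grown in RPMI medium with serum and treated for 5 days with DMSO, 20 nM MRTX1719, 300 nM adagrasib or 1 uM belvarafenib, or with MRTX1719 together with either of the other drugs. Doses of the combinations were not given separately in the sources used here. RNA was extracted with a Qiagen RNeasy Plus Universal Mini kit and made into libraries with an ABclonal mRNA-seq kit, per the labels' protocols. Each of the 6 groups held 3 libraries, which the series' design text calls biological samples, and no further detail on how the replicates were made was given in the sources used here. P values therefore measure only the spread between these libraries, which may be technical.

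Labels conflict for one drug. The sample titles and the treatment text name adagrasib, while the series text calls the same arm an ERK inhibitor and the library names of that arm and of its combination abbreviate another compound name. The conflict cannot be settled from the counts, so adagrasib, also where written without a qualifier or in the name of the combination, is the label of the arm and not an identified drug.

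The authors deposited one table of raw counts per gene, with whole numbers for 60708 gene identifiers in 18 library columns, all of which were used. Reads were aligned with STAR 2.5.2b and the build was GRCh38, per the submitters' processing notes. The counting program, the annotation release and the strand setting were not given in the sources used here. Counts of near-identical paralogs, of overlapping genes and of antisense partners are therefore uncertain. Every row of the deposited table carried a gene identifier, so it holds no tally of reads that were not assigned to a gene. In 25256 rows no library had a count, and 44 rows were second copies of pseudoautosomal genes. Symbols were found for 60507 identifiers. Positions were taken from GENCODE 29 on GRCh38 and are 1-based; 58440 identifiers matched that release without their version number and 37347 with the same version, so gene bounds can differ slightly from those the authors counted over.

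Library totals ran from 34.886 to 46.515 M counts. Intervals and floors given here cover counting error only, because reads without molecular identifiers are not independent molecules. A count of 0 over a group or over all libraries was read as an upper limit of 3 counts of the summed total. Where every library of a group was at 0, a fold is given as a lower bound against 3 counts over the group. Where a group held 1 to 3 counts, the ratio of counts is given with its 95% interval.

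Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1): TMM normalization factors, the filterByExpr filter on the groups, which kept 18557 genes and removed 42151, a robust quasi-likelihood fit on group means of all 18 libraries with 12 residual degrees of freedom, and edgeR's quasi-likelihood F-test for 13 contrasts. P values were 2-sided and adjusted by Benjamini-Hochberg over all genes tested, and adjusted p under 0.05 is called a change. The biological coefficient of variation was 5.82%. An exact permutation of 3 libraries against 3 cannot give a p below 0.1, so single-gene statements rest on the model's pooled spread. The contrasts were each drug and each combination against DMSO, each combination against its single agents, the pair of partner drugs against each other, the combinations against each other, and for each combination the interaction, which is its log2 change minus the sum of the log2 changes of its single agents. Log2 changes are given with a standard error (SE), taken as the fitted log2 change over the square root of the F statistic. For large changes with few counts in a group this SE can be smaller than the counting error. For CPA4, with 14 counts in DMSO, it was 0.323 at a change of 5.851 and 0.204 at 10.735. Group levels are given as mean TMM-scaled CPM, counts scaled to a library of 1e+06, with their SD, n = 3.

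The 34 gene lists, the contrasts, the tests and the rule for named genes were fixed before the data were examined. Lists were tested on the same model with camera and an inter-gene correlation estimated per list, 2-sided, with adjustment over the lists within a contrast; 32 lists with at least 5 genes tested entered. Counts of list members are given over all genes tested and, where they differ, also adjusted over the list alone. Every list call printed is one that holds with the estimated correlation. Among the lists described, camera's preset correlation of 0.01 added 8 calls and ended none. A second list test, limma's fry, added 9 and ended none. All added calls were lists of MAPK, G1/S, G2/M or p53 genes described as missing their test against DMSO. Median, mean and test did not differ in sign for any list past its test. Named genes were the 5 called genes with the largest rise and the 5 with the largest fall per contrast, with at least 5 CPM in the higher group, libraries that did not overlap between the groups (3 against 3 do so by chance in 10% of genes) and no clone or non-coding placeholder name; up to 4 called members of each described list with the smallest adjusted p; and a fixed panel that included PRMT5, MTAP, CDKN2A, MAT2A, DUSP6, SPRY4, ETV4, CCND1, MYC, CDKN1A, MKI67, EGFR and ERBB3 against DMSO.

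The pipeline was tested on simulated data drawn from the DMSO means with the depths and fitted spread of all libraries. Few genes were changed, equally up and down. The simulation therefore does not test normalization where many genes change, as in the real contrasts. In the simulated MRTX1719 against DMSO comparison, 64.29% of 98 genes changed by 0.5 on the log2 scale and 82.11% of 95 genes changed by 1 were called, all with the right sign, and 6% of calls were false. In the simulated interaction of MRTX1719 with adagrasib the shares were 50% and 66.32%, with 7.44% false calls.

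Alternatives planned before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter filter of 1 CPM in 3 libraries and a mean of 50 counts, a fit with the replicate number as a block, a fit on the groups compared only, each library left out in turn, and for lists the preset correlation and limma's fry. Scaling by library totals was added after seeing the data, because abundant transcripts took different shares of the counts between groups: EEF1A1 held 5.10% of counts in DMSO and 2.13% in belvarafenib. No library was left out of the main results.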

Results

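Messenger RNA was counted in 18 libraries of LU99 lung cancer cells, 3 for each of 6 groups. The groups were DMSO, MRTX1719, the group labelled adagrasib, belvarafenib, and MRTX1719 combined with either partner drug. MRTX1719 is known as an inhibitor of PRMT5, an enzyme that methylates arginines in splicing factors, histones and other proteins, and it acts best where the MTAP gene is lost. Belvarafenib is known as an inhibitor of RAF kinases. The sample titles name adagrasib for the remaining arm, but the series text calls that arm an ERK inhibitor, so its drug is uncertain. The series title asks for the effect of each inhibitor and of the combinations on these cells.

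Mean library totals were 42.2 ± 2.94 M counts in DMSO (SD, n = 3 in every group), 40.7 ± 1.104 in MRTX1719, 37.4 ± 3.79 in the adagrasib-labelled group and 40.8 ± 5.06 in belvarafenib. The combinations had 40.7 ± 4.96 M with adagrasib and 41.1 ± 1.84 M with belvarafenib. Across genes, log2 levels of libraries of one group correlated at r 0.9847 to 0.9913, and group against group at 0.9292 to 0.981; genes are not independent replicates. Mitochondrially encoded transcripts took 1.72% of counts in DMSO, 2.24% in MRTX1719, 1.91% in the adagrasib-labelled group, 2.01% in belvarafenib, 2.83% in MRTX1719 with adagrasib and 2.54% in MRTX1719 with belvarafenib. In a principal component analysis the first component held 45.2% of the variance and the second 16.65%, and the libraries of each group lay together.

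**Figure D1:**
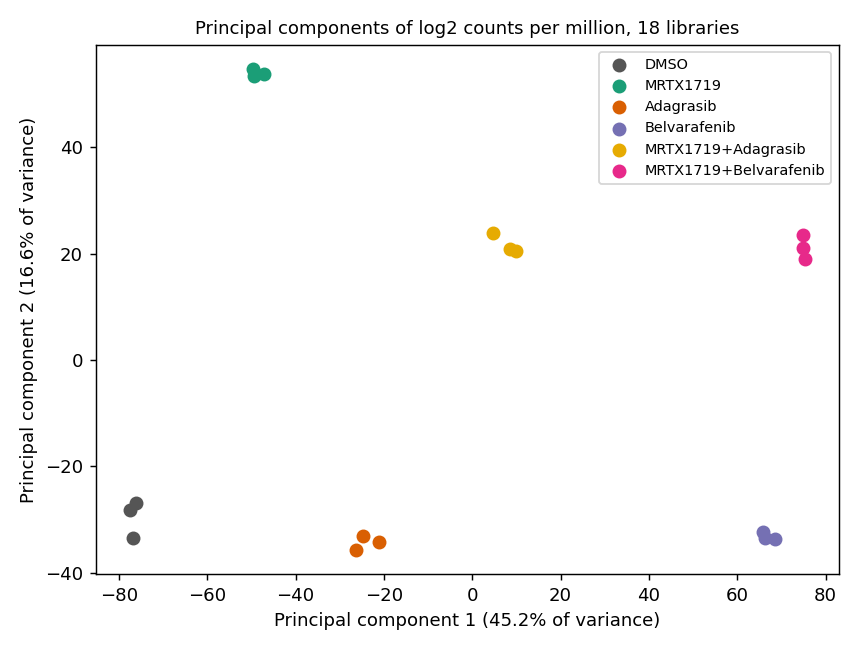
Scores of the 18 libraries on the first and second principal components of log2 expression, one point per library, coloured by group; the axes give 45.2% and 16.65% of the variance. DMSO libraries lie between -77.61 and -76.18 on the first component and belvarafenib libraries between 65.89 and 68.55, while MRTX1719 alone reaches 53.53 to 54.82 on the second.

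No library held a count for MTAP, a methylthioadenosine phosphorylase of methionine salvage, for CDKN2A, which encodes p16 and p14ARF, or for CDKN2B, which encodes p15. They are neighbours on chromosome 9: MTAP at 21802543 to 21937651, CDKN2A at 21967753 to 21995301 and CDKN2B at 22002903 to 22009363. A total of 0 counts in 18 libraries allows at most 0.00412 CPM for each gene. PRMT5 (ENSG00000100462.16, chromosome 14, 22920511 to 22929585) was measured at 49.4 ± 1.51 CPM in DMSO, 37.3 ± 1.56 in MRTX1719, 23.1 ± 1.66 in the adagrasib-labelled group and 15.2 ± 0.366 in belvarafenib. It stood at 21.5 ± 1.40 CPM in MRTX1719 with adagrasib and 15.5 ± 0.952 in MRTX1719 with belvarafenib. Each of these 5 groups was below DMSO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 4.85e-23 in belvarafenib to 1.22e-06 in MRTX1719.

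With MRTX1719 alone, p53 target genes rose and genes of DNA replication and mitosis fell. CDKN1A (ENSG00000124762.14, chromosome 6, 36676460 to 36687339), which encodes the cell cycle inhibitor p21, rose from 278.5 ± 19.1 to 1186 ± 43.9 CPM, a log2 change of 2.09 ± 0.06 (SE, n = 3 per group). MDM2, the ubiquitin ligase that limits p53, rose by 1.41 ± 0.05 and ZMAT3, an RNA-binding p53 target, by 1.45 ± 0.04. MKI67, the proliferation marker Ki-67, decreased by 2.10 ± 0.15 on the log2 scale, from 213 ± 17.5 to 49.6 ± 3.46 CPM, and TOP2A, the topoisomerase of dividing cells, fell by 2.93 ± 0.11. Of 30 p53 targets tested 27 were higher and 1 lower (median 1.30, adjusted p 9.05e-05). Among 54 G2/M genes 50 were lower and 2 higher (median -1.64, adjusted p 0.00336), among them NUF2 and HJURP of the kinetochore and centromere at -2.59 ± 0.08 and -2.40 ± 0.08. The 43 G1/S genes gave 40 lower and none higher (median -0.89, adjusted p 0.00805), with the replicative helicase subunit MCM4 at -1.40 ± 0.05 and the replication licensing factor CDC6 at -1.48 ± 0.08.

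Other groups moved with MRTX1719 as well. Homologous recombination and Fanconi genes were lower in 23 of 28 and higher in 2 (median -0.77, adjusted p 4.26e-04), with FANCA at -2.45 ± 0.11 and BRCA1 at -1.70 ± 0.08. SR protein, hnRNP and CLK kinase genes of splicing were lower in 23 of 31 and higher in 1 (median -0.29, adjusted p 0.00753); SRSF3 fell by 0.69 ± 0.04 and HNRNPR by 0.93 ± 0.04. Lysosome and autophagy genes were higher in 25 of 31 and lower in 2 (median 0.54, adjusted p 0.00136), led by the protease CTSL at 1.45 ± 0.04 and the saposin precursor PSAP at 1.05 ± 0.04. Mesenchymal genes were higher in 16 of 21 and lower in none (median 0.91, adjusted p 5.69e-04), with the collagen crosslinker LOX at 2.84 ± 0.08 and COL5A2 at 1.71 ± 0.05. MAPK pathway activity score genes, a published set of ERK-driven transcripts, gave no list call (4 higher and 2 lower of 10, adjusted p 0.366 with an estimated correlation). Among the 4, the phosphatase genes DUSP4 and DUSP6 rose by 1.76 ± 0.09 and 0.91 ± 0.07. The 2 lower members were EPHA2 at -0.535 ± 0.078 and SPRY4 at -0.275 ± 0.056. The largest rises included carboxypeptidase CPA4 at 5.85 ± 0.32, the hyaluronan-binding CEMIP at 5.00 ± 0.14, complement C3 at 4.51 ± 0.30 and the cytokine IL6 at 4.37 ± 0.20. HES7, a transcriptional repressor, fell by 3.38 ± 0.30 and carbonic anhydrase CA2 by 3.10 ± 0.14. In all, 5093 genes were higher and 4631 lower of 18557 tested, 2223 of them by at least 2-fold. With library totals the majority turned, to 4171 higher and 5608 lower.

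In the group labelled adagrasib, genes that ERK signalling is known to drive fell. Cell cycle genes were not called as lists with the estimated correlation. SPRY4 (ENSG00000187678.10, chromosome 5, 142310427 to 142326455), a feedback inhibitor of the RAS pathway, went from 254 ± 9.44 to 19.0 ± 1.07 CPM, a log2 change of -3.74 ± 0.07. DUSP6 (ENSG00000139318.8, chromosome 12, 89347232 to 89353271), an ERK phosphatase, went from 80.4 ± 1.93 to 18.7 ± 0.827 CPM (-2.10 ± 0.07). MKI67 was higher at 324 ± 37.8 CPM, a log2 change of 0.61 ± 0.14 (adjusted p 0.00262). Of 10 MAPK pathway activity score genes 8 were lower (9 adjusted over the list alone) and none higher (median -1.13, adjusted p 4.31e-04). Other ERK feedback and immediate early genes were lower in 19 of 24 and higher in 5 (median -0.68, adjusted p 2.36e-04), with the transcription factors EGR1 at -8.13 ± 0.13 and FOS at -4.56 ± 0.20 and the phosphatase DUSP5 at -4.38 ± 0.10.

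The same group showed higher antigen presentation genes, 16 of 20 with 1 lower (median 0.74, adjusted p 0.00583), among them the peptide-loading factor TAPBP at 1.32 ± 0.05 and HLA-B at 0.91 ± 0.05. Endoplasmic reticulum chaperone genes were higher in 16 of 18 (median 0.57, adjusted p 0.0252), led by CALR at 1.11 ± 0.05, and fatty acid synthesis genes in 12 of 15 (median 0.55, adjusted p 0.0286), with the desaturase FADS2 at 1.27 ± 0.06; neither list had a lower member. Mesenchymal genes were higher in 11 of 21 (12 adjusted over the list alone) and lower in 5 (median 1.21, adjusted p 2.57e-04), and YAP/TAZ targets higher in 12 of 21 and lower in 5 (6 adjusted over the list alone; adjusted p 0.00616), with TGFB2 at 3.29 ± 0.10 and the ectonucleotidase NT5E at -1.93 ± 0.05. NF-kB targets and inflammatory cytokines were lower in 13 of 23 and higher in 5 (15 and 7 adjusted over the list alone; median -0.62, adjusted p 0.0286): IL1A fell by 2.39 ± 0.06, while IL6 rose by 4.61 ± 0.19. BCL2 family genes were lower in 6 of 14 and higher in 1 (adjusted p 0.0428), with the survival factor MCL1 at -1.55 ± 0.04 and the pro-apoptotic HRK at -0.98 ± 0.07. This list lost its call with the replicate number as a block. G1/S genes (25 higher, 2 lower of 43; 26 higher adjusted over the list alone), G2/M genes (43 higher, 1 lower of 54) and p53 targets (16 higher, 7 lower of 30; 8 lower adjusted over the list alone) missed the list test with adjusted p 0.512, 0.342 and 0.203 with an estimated correlation. The largest rises included CPA4 at 8.02 ± 0.24 and the acute-phase gene SAA1 at 6.36 ± 0.29. CPA4 and SAA1 held 14 and 10 counts in DMSO, so their SEs are smaller than the counting error. The largest falls included the collagenase MMP1 at -8.59 ± 0.21 and the secreted glycoprotein STC1 at -7.28 ± 0.24. Counts were 4256 genes higher and 3669 lower, 1363 by at least 2-fold. Small panel changes did not keep their call with every library left out, which also leaves fewer libraries to test. MYC at 0.14 ± 0.05 (adjusted p 0.0128) lost its call without adagrasib-labelled replicate 2 (0.101) or 3 (0.057), and CDKN1A at -0.18 ± 0.05 (adjusted p 0.00772) without DMSO replicate 2 (0.0682).

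Belvarafenib lowered the same MAPK targets to about 1 CPM. SPRY4 was at 1.07 ± 0.312 CPM (-7.88 ± 0.10), DUSP6 at 0.775 ± 0.0224 (-6.69 ± 0.11) and the ETS factor ETV4 at 1.31 ± 0.256 against 75.9 ± 1.71 in DMSO (-5.84 ± 0.14). Cyclin D1 (CCND1) fell from 167 ± 6.76 to 41.9 ± 1.26 CPM and MYC from 174 ± 2.41 to 39.3 ± 1.37 CPM. MAPK pathway activity score genes were lower in 9 of 10 and higher in 1 (median -4.20, adjusted p 1.31e-04). Other ERK feedback and immediate early genes were lower in 20 of 24 and higher in 1 (median -1.80, adjusted p 1.31e-04), with the AP-1 gene FOSL1 at -6.40 ± 0.07 and the chromatin factor HMGA2 at -4.07 ± 0.07.

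Genes for ribosomes and their assembly fell with belvarafenib. Cytosolic ribosomal protein genes were lower in 61 of 61 (median -1.22, adjusted p 0.042), with RPL4 going from 3917 to 1336 CPM (-1.55 ± 0.04), and ribosome biogenesis genes in 29 of 30 with none higher (median -0.92, adjusted p 0.0112), such as the nucleolar methyltransferase FBL at -1.94 ± 0.05 and NPM1 at -1.45 ± 0.04. Ribosomal protein genes have many processed copies, so single members are uncertain. Methionine cycle, salvage and polyamine genes were lower in 16 of 21 and higher in 2 (median -0.45, adjusted p 0.0159), among them the SAM synthetase MAT2A at -0.98 ± 0.05. Antigen presentation genes were higher in 16 of 20 and lower in none (median 1.21, adjusted p 0.0105), with HLA-B at 1.67 ± 0.05, and lysosome and autophagy genes higher in 25 of 31 and lower in 4 (median 0.90, adjusted p 0.0057), with PSAP at 1.99 ± 0.04 but CTSL at -1.79 ± 0.04. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, were higher in 11 of 12 and lower in 1 (median 2.30, adjusted p 0.026), with H2AC6 at 3.14 ± 0.09 and H1-2 at 2.60 ± 0.15. Mesenchymal genes were higher in 14 of 21 and lower in 5 (median 1.57, adjusted p 8.58e-04), with COL1A1 going from 1.08 to 84.4 CPM (6.28 ± 0.11) and SPARC at 3.12 ± 0.05, and YAP/TAZ targets higher in 10 of 21 and lower in 5 (adjusted p 0.026), with TGFB2 at 6.16 ± 0.09. NF-kB targets and inflammatory cytokines were lower in 17 of 23 and higher in 5 (median -1.67, adjusted p 0.0163). G1/S genes (36 lower, 1 higher of 43) and G2/M genes (24 lower, 8 higher of 54) missed the list test, with adjusted p 0.227 and 0.714 with an estimated correlation, and p53 targets (21 higher, 6 lower of 30) with 0.0524, although TP53I3 rose by 4.36 ± 0.09. The p53 result depended on the fit, as the list was called with the replicate number as a block. CCN5, a matricellular protein gene at 0 counts in DMSO, was at least 1458-fold higher at 34.5 ± 3.61 CPM, and the deiodinase DIO2 rose by 13.18 ± 0.41. MMP1 fell by 12.88 ± 0.30 and the endothelial-type proteoglycan gene ESM1 by 10.50 ± 0.30. MMP1 held 8 counts in belvarafenib, so its SE is smaller than the counting error. In total 6033 genes were higher and 5725 lower, 4119 by at least 2-fold.

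**Figure D2:**
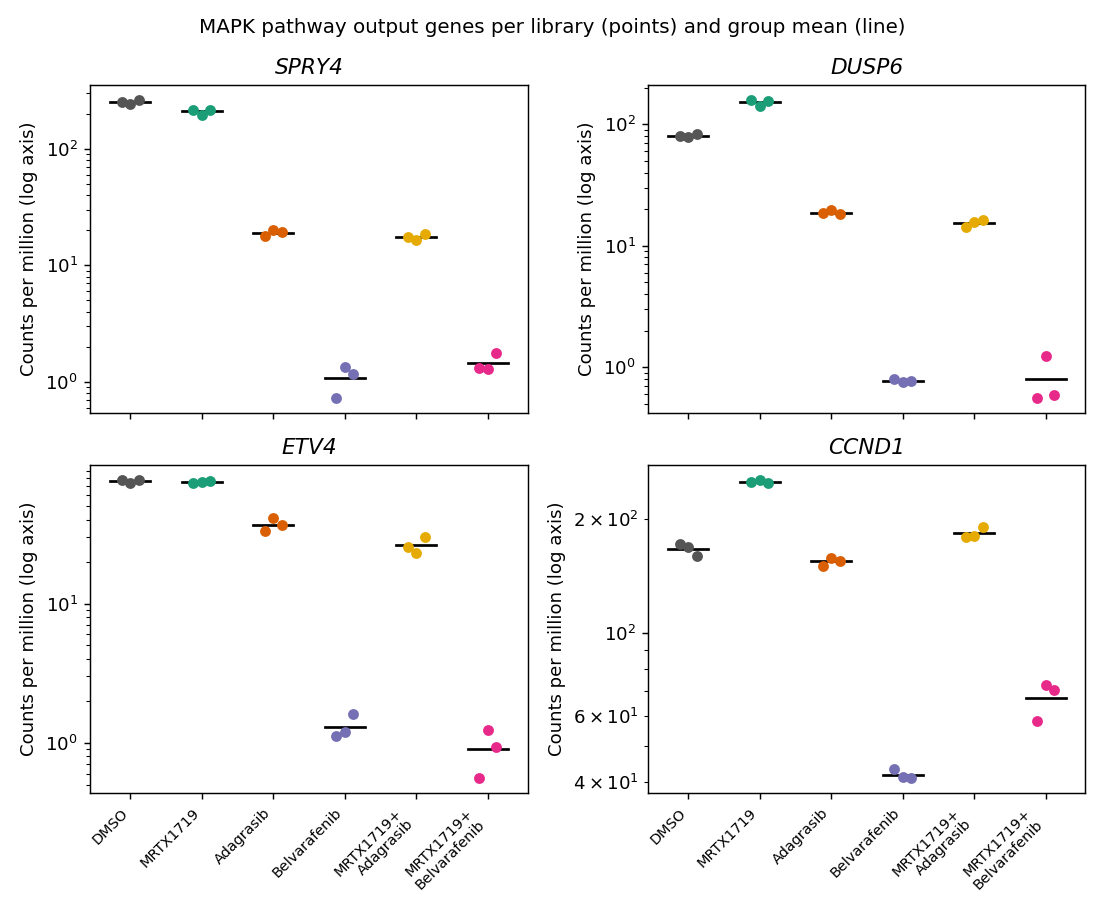
CPM per library on a log axis for genes of the MAPK output panel in the 6 groups, with points for the 3 libraries and lines for group means. SPRY4 averages 254 CPM in DMSO, 19.0 in the adagrasib-labelled group and 1.07 in belvarafenib. In MRTX1719 alone SPRY4 averages 210 and DUSP6 151.

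Set side by side, the partner drugs at their single doses differed in MAPK output and in single genes such as IGFBP3 and COL1A1. DUSP6 was higher with the adagrasib label than with belvarafenib by 4.59 ± 0.13 on the log2 scale, FOSL1 by 5.47 ± 0.06 and MYC by 2.28 ± 0.05. The insulin-like growth factor binding protein IGFBP3 was at 8.49 CPM against 1577 CPM in belvarafenib (-7.54 ± 0.22), COL1A1 at -5.23 ± 0.10, and BMF, a pro-apoptotic BCL2 family gene, at -4.91 ± 0.10. Higher members numbered 9 of 10 with 1 lower for the MAPK pathway activity score (adjusted p 7.26e-04), 13 of 24 with 6 lower for other ERK feedback genes (adjusted p 0.00329), 42 of 43 for G1/S genes (adjusted p 0.0393), 60 of 61 for ribosomal protein genes (adjusted p 0.0425), 29 of 30 for ribosome biogenesis genes and 22 of 28 for homologous recombination genes (both adjusted p 0.00903). None of these last 4 lists had a lower member. ATF4 and amino acid response genes were higher in 24 of 28 and lower in 3 (adjusted p 0.0425), with the glutathione-degrading CHAC1 at 3.67 ± 0.11, methionine cycle genes higher in 14 of 21 and lower in 3 (16 higher adjusted over the list alone; adjusted p 0.0285), and NF-kB targets higher in 15 of 23 and lower in 4 (adjusted p 0.0393). Lower with the adagrasib label were lysosome genes (23 of 31, 4 higher, adjusted p 0.00903), histone genes (9 of 12, none higher, 1 higher adjusted over the list alone, adjusted p 0.0337), BCL2 family genes (8 of 14, 2 higher, 3 adjusted over the list alone, adjusted p 0.0393), epithelial genes (10 of 16, 3 higher, adjusted p 0.0446) and mesenchymal genes (11 of 21, 12 adjusted over the list alone, 7 higher, adjusted p 0.0191). Among them were the adhesion genes JUP at -1.48 ± 0.06 and EPCAM at -1.33 ± 0.08. With the replicate number as a block, the calls of the G1/S, ribosomal protein, BCL2 family and epithelial lists ended. Gene calls numbered 5039 higher and 4949 lower. The drugs were compared at 300 nM and 1 uM, so dose and drug are not separated.

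MRTX1719 with adagrasib, against DMSO, joined the fall in MAPK targets with the rise in p53 targets. Cell cycle genes were not called as lists with the estimated correlation. SPRY4 was at 17.6 ± 1.05 CPM (-3.85 ± 0.07), DUSP6 at 15.4 ± 1.07 CPM (-2.39 ± 0.07) and CDKN1A at 665 ± 45.4 CPM (1.26 ± 0.05). MKI67 was at 317 ± 40.1 CPM (0.58 ± 0.14, adjusted p 0.00263). MAPK pathway activity score genes were lower in 8 of 10 and higher in 2 (median -1.40, adjusted p 0.00518) and other ERK feedback genes lower in 19 of 24 and higher in 3 (adjusted p 9.17e-04). Of 30 p53 targets 24 were higher and 5 lower (median 1.03, adjusted p 9.17e-04), with MDM2 at 1.63 ± 0.05 and TP53I3 at 3.29 ± 0.09. G1/S genes (13 higher, 11 lower of 43, median -0.03) and G2/M genes (25 higher, 12 lower of 54, median 0.13) each had adjusted p 0.865 with an estimated correlation. Mesenchymal genes were higher in 16 of 21 and lower in 5 (median 1.49, adjusted p 1.54e-04), with COL5A2 at 3.30 ± 0.05, and YAP/TAZ targets higher in 13 of 21 and lower in 3 (4 adjusted over the list alone; adjusted p 0.00298), with the muscle repeat protein gene ANKRD1 at 6.15 ± 0.16. CPA4 rose by 10.74 ± 0.20 from 0.111 to 193 CPM; AMTN, with 1 count in DMSO, had a count ratio of 799 (95% interval 143 to 31600); and KRT34, a hair keratin, fell by 6.21 ± 0.10. There were 5497 genes higher and 5237 lower, 2867 by at least 2-fold. CCND1 at 0.14 ± 0.05 (adjusted p 0.0207) lost its call without DMSO replicate 3 (0.121) or MRTX1719 with adagrasib replicate 3 (0.106).

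Against MRTX1719 alone, that combination had higher cell cycle genes. The kinesin KIF23 rose from 13.5 to 78.4 CPM (2.53 ± 0.07), the spindle protein gene DLGAP5 from 9.53 to 59.5 CPM (2.64 ± 0.08) and cyclin B1 (CCNB1) from 37.6 to 161 CPM (2.10 ± 0.05). G2/M genes were higher in 52 of 54 (53 adjusted over the list alone; median 1.77, adjusted p 0.00182) and G1/S genes in 41 of 43 (median 0.84, adjusted p 0.00786), with none lower. Homologous recombination genes were higher in 21 of 28 and lower in 4 (22 higher adjusted over the list alone; adjusted p 0.00182), cyclin, CDK and CDK inhibitor genes higher in 13 of 19 and lower in 3 (4 adjusted over the list alone; adjusted p 0.0111), and splicing factor genes higher in 20 of 31 and lower in 2 (21 higher adjusted over the list alone; adjusted p 0.034). Lower members numbered 9 of 10 in the MAPK pathway activity score (adjusted p 3.1e-04), 21 of 24 among other ERK feedback genes with 1 higher (adjusted p 9.36e-05), 18 of 31 lysosome genes with 7 higher (adjusted p 0.0251), 9 of 14 BCL2 family genes with 3 higher (adjusted p 0.00786) and 12 of 23 NF-kB targets with 6 higher (13 lower adjusted over the list alone; adjusted p 0.00927). CTSL fell by 2.77 ± 0.04 and PMAIP1, which encodes the p53-induced NOXA, by 1.92 ± 0.05. YAP/TAZ targets (13 higher, 4 lower of 21, 14 higher adjusted over the list alone; adjusted p 0.00697) and mesenchymal genes (13 higher, 6 lower of 21; adjusted p 0.0053) were also called. With TMM 49.93% of calls were higher, but 65.16% with library totals, which placed the median gene at 0.1257 on the log2 scale. The G2/M median with library totals was 1.88.

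Against the adagrasib-labelled drug alone, p53 targets were higher in 21 of 30 and lower in 4 (median 0.88, adjusted p 1.72e-04), with the antiproliferative BTG2 at 1.89 ± 0.08. ATF4 and amino acid response genes were lower in 26 of 28 and higher in none (median -0.93, adjusted p 0.0162), with CHAC1 going from 61.3 to 13.6 CPM (-2.17 ± 0.10) and the stress factor DDIT3 at -1.77 ± 0.09. Homologous recombination genes were lower in 15 of 28 and higher in 1 (adjusted p 0.0162). Among 21 mesenchymal genes 13 were higher and 5 lower (adjusted p 7.81e-04), with the gelatinase MMP2 at 2.16 ± 0.08, and YAP/TAZ targets higher in 10 of 21 and lower in 4 (5 adjusted over the list alone; adjusted p 0.0162). The glutamate transporter SLC1A3 rose by 3.70 ± 0.20 and the interferon-induced OAS2 fell by 2.78 ± 0.24. Calls against MRTX1719 were 4432 higher and 4444 lower, and against the adagrasib-labelled drug 3854 and 3906.

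**Figure D3:**
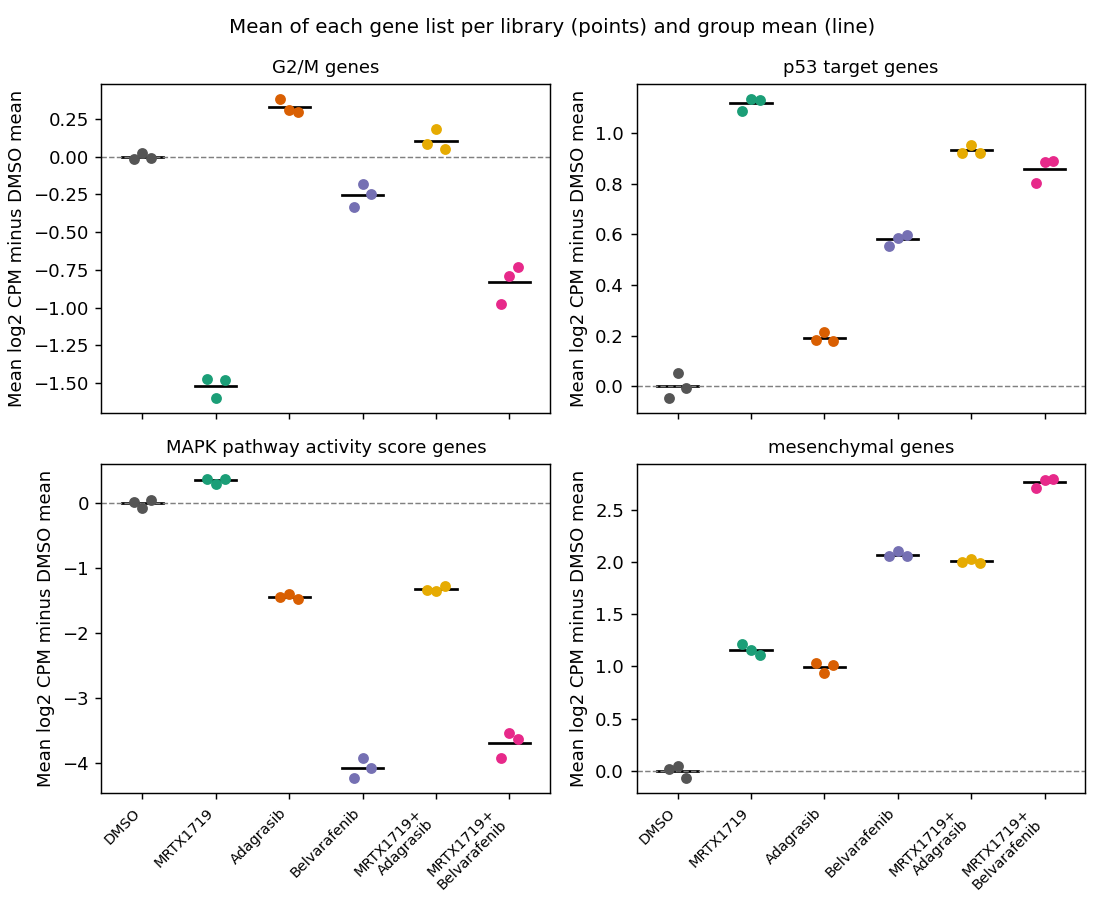
Mean log2 level of gene lists relative to DMSO, one point per library in each of the 6 groups. For the MAPK pathway activity score genes the group means are 0.35 in MRTX1719, -1.44 in the adagrasib-labelled group and -4.08 in belvarafenib.

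With MRTX1719 and belvarafenib together, MAPK targets were lower and p53 targets higher than in DMSO. SPRY4 was at 1.46 ± 0.277 CPM (-7.43 ± 0.09), DUSP6 at 0.791 ± 0.382 (-6.68 ± 0.11) and CDKN1A at 921 ± 50.5 CPM (1.73 ± 0.05). MKI67 was lower at 119 ± 15.5 CPM (-0.84 ± 0.14, adjusted p 1.2e-04). MAPK pathway activity score genes were lower in 9 of 10 and higher in 1 (median -3.78, adjusted p 2.42e-04), other ERK feedback genes lower in 18 of 24 and higher in 1 (adjusted p 3.54e-04), and p53 targets higher in 22 of 30 and lower in 7 (median 0.86, adjusted p 0.0173), with TP53I3 going from 2.88 to 130 CPM (5.49 ± 0.09). Homologous recombination genes were lower in 23 of 28 with none higher (adjusted p 0.0173). G1/S genes (39 lower, none higher of 43) and G2/M genes (47 lower, 3 higher of 54) had adjusted p 0.0911 and 0.186 with an estimated correlation. Among 21 mesenchymal genes 15 were higher and 3 lower (median 2.66, adjusted p 2.42e-04): COL1A1 rose by 7.59 ± 0.11 to 210 CPM and SPARC by 3.84 ± 0.05. YAP/TAZ targets (13 higher, 7 lower of 21; adjusted p 0.0181) and lists for histones (10 higher, 1 lower of 12), lysosome (22 higher, 8 lower of 31), ribosome biogenesis (27 lower, 1 higher of 30), methionine cycle (15 lower, 3 higher of 21) and NF-kB targets (17 lower, 5 higher of 23; 18 lower adjusted over the list alone) were called as well, these 5 with adjusted p 0.0246. DIO2 rose by 13.69 ± 0.41, GASK1B, with 1 count in DMSO, had a count ratio of 3510 (95% interval 630 to 139000), and SLC14A1, a urea transporter, fell by 8.19 ± 0.23. With TMM 6221 genes were higher and 6221 lower, 4796 by at least 2-fold. Library totals gave 5728 higher and 6728 lower, and RLE factors 6353 and 6085.

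Against MRTX1719 alone the belvarafenib combination had 5402 genes higher and 5418 lower. DUSP6 fell by 7.59 ± 0.11 and FOSL1 by 6.05 ± 0.07, while MMP2 rose from 9.66 to 278 CPM (4.85 ± 0.08). MAPK pathway activity score genes were lower in 9 of 10 with 1 higher (adjusted p 2.75e-05), other ERK feedback genes in 20 of 24 with 2 higher (adjusted p 3e-05) and NF-kB targets in 17 of 23 with 4 higher (adjusted p 0.00707); mesenchymal genes were higher in 12 of 21 and lower in 8 (adjusted p 0.0019). G2/M genes were individually higher in 42 of 54 and lower in 4 (median 0.74) with adjusted p 0.437 with an estimated correlation. Against belvarafenib alone, interferon-stimulated genes were lower in 30 of 36 and higher in none (median -0.90, adjusted p 0.0193): OAS2, an antiviral RNA sensor, fell from 9.64 to 0.836 CPM (-3.54 ± 0.26) and IFI6 fell by 2.59 ± 0.23. Antigen presentation genes were lower in 13 of 20 and higher in 1 (adjusted p 0.0193), with the immunoproteasome subunit PSMB8 at -1.04 ± 0.06, and homologous recombination genes lower in 15 of 28 and higher in 2 (adjusted p 0.0184). Mesenchymal genes were higher in 14 of 21 and lower in 2 (adjusted p 0.00182), with TGFBI at 2.03 ± 0.09, and p53 targets higher in 20 of 30 and lower in 3 (22 higher adjusted over the list alone; adjusted p 0.0396). The ephrin receptor EPHA3 rose by 4.14 ± 0.39. Of the calls against belvarafenib 3803 were higher and 3458 lower, a share of 52.38% higher that was 31.63% with library totals.

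Between the combinations, cell cycle and MAPK genes were higher with adagrasib. G2/M genes were higher in 49 of 54 and lower in 1 (median 1.09, adjusted p 0.0245), with the chromatin protein gene HMGB2 at 1.46 ± 0.05, and G1/S genes in 41 of 43 with none lower (median 0.80, adjusted p 0.0117). The MAPK pathway activity score genes (9 higher, 1 lower of 10; adjusted p 2.19e-04), other ERK feedback genes (13 higher, 6 lower of 24; adjusted p 0.00444), homologous recombination genes (20 higher, 1 lower of 28, 22 higher adjusted over the list alone; adjusted p 0.00444), ribosome biogenesis genes (26 higher, none lower of 30; adjusted p 0.0295) and NF-kB targets (17 higher, 4 lower of 23; adjusted p 0.0296) went the same way. Lysosome genes (21 lower, 5 higher of 31, 6 higher adjusted over the list alone; adjusted p 0.0295), BCL2 family genes (8 lower, 2 higher of 14; adjusted p 0.0155), epithelial genes (10 lower, 2 higher of 16; adjusted p 0.0117) and mesenchymal genes (12 lower, 3 higher of 21; adjusted p 0.0117) were lower with adagrasib. ACKR3, a chemokine scavenging receptor, was at 0.828 against 77.3 CPM (-6.56 ± 0.13). There were 4445 genes higher and 4273 lower; the share higher was 50.99%, or 63.48% with library totals, which placed the median gene at 0.1172.

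For each combination the interaction asked whether the log2 change differed from the sum of its single agents. With adagrasib, G2/M genes lay above the sum in 48 of 54 (50 adjusted over the list alone; median 1.35, adjusted p 0.00135) and lysosome genes below it in 25 of 31 (median -0.52, adjusted p 3.11e-04), DLGAP5 at 2.31 ± 0.10 and CTSL at -1.63 ± 0.06. With belvarafenib, p53 targets lay below the sum in 26 of 30 and above it in none (1 adjusted over the list alone; median -0.77, adjusted p 2.87e-04), with CDKN1A at -1.69 ± 0.08, and interferon-stimulated genes in 27 of 36 (median -0.69, adjusted p 0.0413). SAA1 was at -6.03 ± 0.34 and IL6 at -4.65 ± 0.23 there. The interferon-stimulated list lost its call in the belvarafenib interaction with the replicate number as a block. The interaction was called for 2136 genes above and 2918 below the sum with adagrasib (42.26% above, 57.89% with library totals) and for 3133 above and 3493 below with belvarafenib. Of 3891 genes called in the same direction in MRTX1719 and the adagrasib-labelled drug, the interaction ran against that direction in 1959 and with it in 105; for belvarafenib these were 3680 and 67 of 5575. Both single-agent contrasts share the DMSO libraries, whose chance error can pull the interaction this way.

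**Figure D4:**
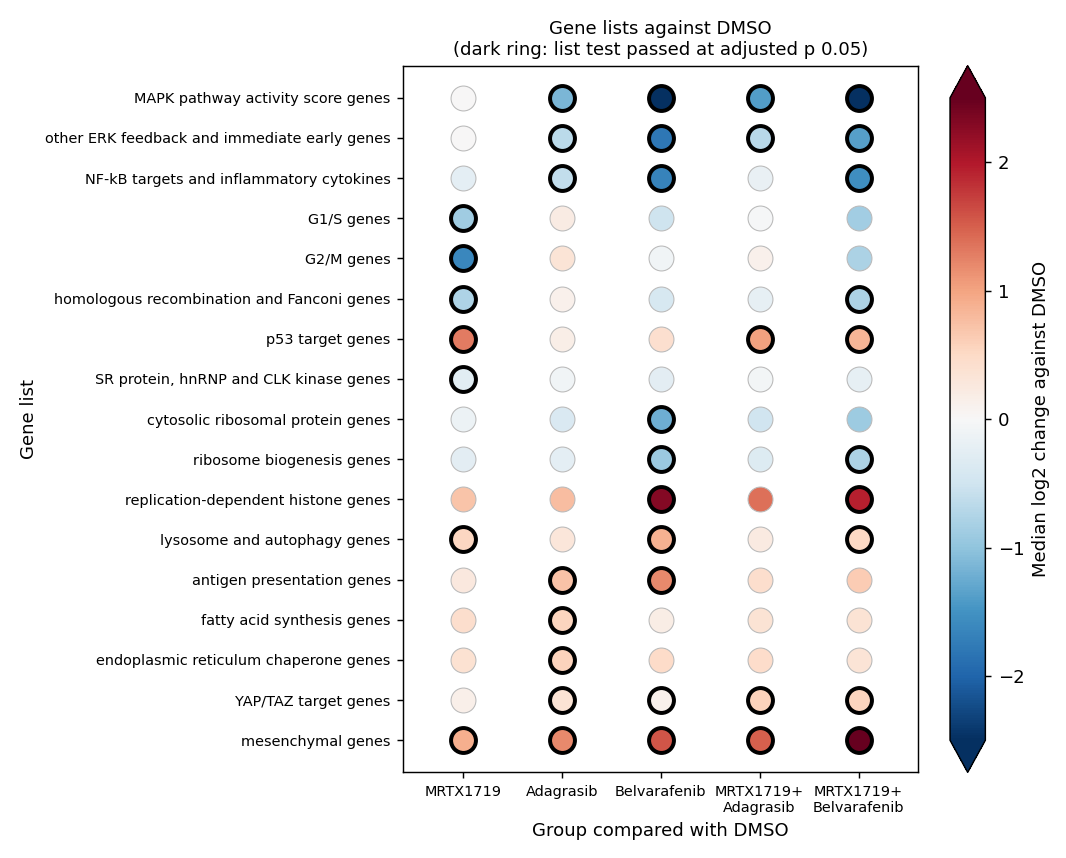
Median log2 change of a selection of the gene lists in each treated group against DMSO, as a colour scale with one circle per list and group. A dark ring marks a list past its test. The G2/M median is -1.64 for MRTX1719 and 0.13 for MRTX1719 with adagrasib.

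MRTX1719's effect was compared with and without a partner drug in contrasts that share no library. Fitted log2 changes of MRTX1719 against DMSO and of its addition to the adagrasib-labelled drug correlated at r 0.5271 across 18557 genes (jackknife SE 0.0308), and with its addition to belvarafenib at 0.3859 (SE 0.0334). In the first pair 2653 genes were higher in both contrasts, where independent lists would share 1057.7, and 2592 lower in both against 974.8; in the second 2114 were higher and 2038 lower, against 1043.7 and 863. The adagrasib-labelled drug against DMSO and the addition of belvarafenib to MRTX1719 correlated at 0.4436 (SE 0.0333), and belvarafenib against DMSO with the addition of the adagrasib-labelled drug to MRTX1719 at 0.5416 (SE 0.026). Genes beyond both single agents in one direction numbered 3069 with adagrasib, 1507 higher and 1562 lower, among them CPA4, MMP2, TGFB2 and COL5A2, each higher than with either single agent. With belvarafenib there were 2820, 1602 higher and 1218 lower, among them COL1A1, SPARC and COL5A2. Without the filter for low counts these 4 correlations were 0.1515, 0.1161, 0.149 and 0.1951, in the order given. In the filtered data, with any one library left out each was lower than the value given. The filter was run again each time, so the genes entering could change too. The fall can therefore not be assigned to a library, and the jackknife SE rests on those refiltered values.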

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

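The tests of the G2/M pattern below, the test narrowed to genes with at least 5 CPM in DMSO and the test of S phase were chosen after the result was seen. What drew attention here was a test of a difference itself, the interaction of MRTX1719 with its partner drug. It asks whether the effect of MRTX1719 was the same with and without the partner. With adagrasib it was called for 5054 genes and with belvarafenib for 6626.

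Cell cycle genes lay above the sum of the single agents with adagrasib. G1/S genes had a median of 0.647 (38 above, none below of 43, 40 above adjusted over the list alone; adjusted p 0.00617) with the helicase BRIP1 at 1.531, and G2/M genes 1.351 with the spindle gene DLGAP5 at 2.312. Cyclins, CDKs and CDK inhibitors had 0.088 (8 above, 3 below of 19; adjusted p 0.0394) with CCNB1 at 1.751, homologous recombination and Fanconi genes 0.47 (19 above, none below of 28; adjusted p 0.00135) with FANCI at 0.985, and splicing factor genes 0.354 (23 above, 1 below of 31, 2 below adjusted over the list alone; adjusted p 0.00189) with SRSF3 at 0.641. Below the sum lay p53 targets at -0.336 (19 of 30, 21 adjusted over the list alone, 3 above; adjusted p 0.0194) with PLK2 at -1.405, antigen presentation genes at -0.561 (12 of 20, 13 adjusted over the list alone; adjusted p 0.00376) with TAPBP at -1.144, fatty acid synthesis genes at -0.544 (12 of 15; adjusted p 0.00376) with SCD at -0.93 and endoplasmic reticulum chaperone genes at -0.324 (14 of 18, 16 adjusted over the list alone; adjusted p 0.0333) with CALR at -1.046. Lysosome genes at -0.517 with CTSL at -1.625 and mesenchymal genes at -0.309 (11 of 21, 2 above, 3 above adjusted over the list alone; adjusted p 0.00645) with LOX at -1.93 did so as well. Single genes furthest above were SCN9A at 2.593, COL12A1 at 2.43, KIF18B at 2.415, CXCL8 at 2.376 and TROAP at 2.357, and furthest below SERPINB7 at -3.355, EVI2B at -3.254, COLEC12 at -3.237, CPA4 at -3.14 and CEMIP at -3.087, among the genes that met the naming rule. Of these, EVI2B and CPA4 held 10 and 14 counts in DMSO, and CXCL8 held 18 in the adagrasib-labelled group.

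With belvarafenib many of the same lists were called. Above the sum were G1/S genes at 0.592 (35 of 43, 38 adjusted over the list alone; adjusted p 0.0353) with BRIP1 at 1.532, G2/M genes at 1.015 (50 of 54, 52 adjusted over the list alone; adjusted p 0.0194) with HJURP at 1.831, splicing factor genes at 0.373 (24 of 31, 2 below; adjusted p 0.00195) with SRSF3 at 0.856, ribosome biogenesis genes at 0.366 (21 of 30, 23 adjusted over the list alone; adjusted p 0.0391) with BOP1 at 0.802 and homologous recombination genes at 0.479 (15 of 28, 17 adjusted over the list alone; adjusted p 0.00713) with CHEK1 at 0.897. Below it were p53 targets at -0.767 with PLK2 at -1.294, interferon-stimulated genes at -0.687 with IFIT2 at -1.449, antigen presentation genes at -0.824 (15 of 20, 16 adjusted over the list alone; adjusted p 0.0019) with B2M at -1.018 and fatty acid synthesis genes at -0.672 (10 of 15, none above, 1 above adjusted over the list alone; adjusted p 0.0141) with ME1 at -0.805. Of these, the interferon-stimulated list lost its call with the replicate number as a block. Chaperone genes at -0.592 (14 of 18, 15 adjusted over the list alone, 1 above; adjusted p 0.0194) with CALR at -1.365, lysosome genes at -0.7 (28 of 31; adjusted p 9.74e-05) with PSAP at -1.255 and mesenchymal genes at -0.335 (9 of 21, 2 above; adjusted p 0.0138) with LOX at -1.993 were also below. Single genes above were EPHA3 at 4.503, whose call ended without DMSO replicate 2 (3.46, adjusted p 0.118), MMP1 at 3.615 and NPTX1 at 3.418, and below SAA1 at -6.03, CPA4 at -5.504, IL6 at -4.645, IL7R at -3.836 and ABCA1 at -3.447. KCNK15 and RPSAP52, with 3 counts or fewer in a group, are left out. Several of those named also rest on few counts. MMP1 (SE 0.988) held 8 counts in belvarafenib and 68 in the combination. EPHA3 (SE 1.129) held 10 in DMSO and 7 in MRTX1719. SAA1 and CPA4 held 10 and 14 in DMSO.

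Low G2/M genes in MRTX1719 alone and near-DMSO levels with adagrasib were weighed first. If the combination libraries held cells that saw no active MRTX1719, other genes changed by MRTX1719 would not move; 1116 such genes, outside the cell cycle lists and not called with adagrasib alone, moved by a median of 0.766 in MRTX1719's direction against the adagrasib-labelled drug (quartiles 0.352 and 1.287; 534 called that way and 5 the other), against 1.504 with MRTX1719 alone. Normalization is argued against by an interaction median for G2/M genes of at least 1.349 with RLE factors and with library totals. That the fall is countered whichever partner drug is given stays open: with belvarafenib the G2/M median against MRTX1719 was 0.741, but the list test gave adjusted p 0.437. The interaction with belvarafenib was called for the G2/M list (median 1.015). That call goes with the explanation but was not the test set for it. Unstated combination doses and culture density, for which no value was at hand, also stay open, so the pattern may be technical or biological.

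Combination changes smaller than the sum of the single agents were weighed next, in genes changed at least 2-fold in the same direction by both single agents (502 with adagrasib, 840 with belvarafenib). Shared chance error of the DMSO libraries was to be excluded at a median shortfall of 3 standard errors; the lower of the medians was 2.91, which leaves it open over all these genes. Among the 129 and 237 genes with at least 5 CPM in DMSO, a limit set after that value was seen, the lower median was 8.56, which argues against it for those genes and leaves the less expressed ones open. A floor in counts is argued against for genes that rose, where the median shortfall was at least 1.335 and 376 of 390 and 572 of 581 genes fell short; for genes that fell it stays open. A limit to how far shared targets can change is one biological reading that was not tested and could apply.

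Higher replication-dependent histone transcripts with belvarafenib were weighed last. The rise was not particular to belvarafenib, where the mean log2 level of the list was 2.002 above DMSO. It was 0.69 above in MRTX1719, 0.756 with the adagrasib label, 1.221 in MRTX1719 with adagrasib and 1.907 in MRTX1719 with belvarafenib. With belvarafenib, a larger share of cells in S phase was predicted to raise G1/S genes, whose median was -0.517. That list missed its test, and the share of cells in S phase was not measured. The G1/S levels thus gave no sign of a larger share, but it stays open. More RNA without a poly(A) tail passing selection could not be judged: of 26 such RNAs listed only 4 were tested, with a median of -0.161, a range of -0.549 to 1.144 and 1 called higher. Histone transcripts that gain a poly(A) tail remain a candidate explanation, untested here.

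Other splits of the libraries were fitted with the same model, but on the libraries of the groups compared only, filtered and normalized anew. Counts of the real splits therefore differ from those of the main fit. For 6 libraries in 2 groups there are 10 splits, too few for a share under 0.05; 1 split, the real one, called as many genes in each contrast. The real splits called 9642 genes for MRTX1719, 8186 for the adagrasib-labelled drug, 11681 for belvarafenib, 10598 for MRTX1719 with adagrasib and 11796 for MRTX1719 with belvarafenib, each against DMSO. They called 8784 and 7831 for the adagrasib combination against MRTX1719 and its partner, 10224 and 6684 for the belvarafenib combination, 10106 between the partner drugs and 8071 between the combinations; the highest of the other splits was 0 in each. For the interactions 1 of 50 splits called as many: 5197 genes with adagrasib (highest other 1751) and 6538 with belvarafenib (highest other 0). Genes beyond both single agents gave 3147 (highest other 614) and 2656 (highest other 64), again 1 of 50. These splits moved libraries between all the groups compared, so effects of the single drugs entered the spread within groups. They can therefore not tell whether an interaction, or a change beyond both single agents, exceeds chance.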

How the results depend on the processing

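Scaling by library totals was chosen after the data were seen; the other alternatives were planned. No call of a named gene reversed its direction in these alternatives, and no list call did with fry, the preset correlation or the replicate block, the alternatives run for lists. The majority of calls did turn with library totals: from 52.38% to 42.65% higher for MRTX1719 against DMSO, and 49.93% to 65.16% and 49.93% to 51.9% for the adagrasib and belvarafenib combinations against MRTX1719. It also went from 52.38% to 31.63% for MRTX1719 with belvarafenib against belvarafenib, 50.45% to 49.05% between partner drugs and 42.26% to 57.89% for the adagrasib interaction. With RLE factors it turned between the combinations (50.99% to 48.79%) and for the belvarafenib combination against MRTX1719 (51.22%). The 15 counts of genes stayed within 1.5 times their reported value in every alternative, at ratios of 1.004 to 1.035 with DESeq2, 0.998 to 1.019 with RLE factors, 0.987 to 1.038 with library totals, 0.931 to 1.002 without the low-count filter, 0.847 to 1.002 with the stricter one, 0.912 to 1.033 with only the groups compared and 0.844 to 0.974 with one library left out.

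Similarity of log2 changes moved with the filter. Without it r was 0.1515 for MRTX1719 alone and added to the adagrasib-labelled drug, 0.1161 for MRTX1719 alone and added to belvarafenib, 0.149 for the adagrasib-labelled drug and belvarafenib added to MRTX1719, and 0.1951 for belvarafenib and the adagrasib-labelled drug added to MRTX1719; with the stricter filter these were 0.668, 0.5167, 0.5738 and 0.6092. Leave-one-out values ran from 0.464 to 0.4933, 0.3225 to 0.3568, 0.388 to 0.4214 and 0.4901 to 0.518, all below the values with every library. Of these values 38 moved by more than the jackknife SE and 10 did not. By construction the filters change which weakly expressed genes enter, and the filter was run again with each library left out. The fall in the leave-one-out values can therefore not be assigned to any library.

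With the replicate number as a replicate block the counts were 9810, 8046, 11805, 10827 and 12487 against DMSO (MRTX1719, adagrasib label, belvarafenib, and the combinations in that order), 8988 and 7940 for the adagrasib combination against MRTX1719 and its partner, 10914 and 7434 for the belvarafenib combination, 10099 between partner drugs, 8885 between combinations, 5302 and 6823 for the interactions, and 3185 and 2904 beyond both single agents. Whether the numbers pair the samples is not settled. Only 1 of 45 same-number pairs had residual r over 0.1 (range -0.0234 to 0.102, mean 0.0128 against -0.0064 for other numbers). However, 15 of 18 libraries correlated best with one of their own number, so a weak effect shared by a replicate number cannot be excluded. Under the block 6 list calls ended and 1 was gained: BCL2 family with the adagrasib label (adjusted p 0.0639), G1/S (0.0523), ribosomal protein (0.0523), BCL2 family (0.0525) and epithelial genes (0.0559) between partner drugs, interferon-stimulated genes in the belvarafenib interaction (0.0549), and p53 targets with belvarafenib (0.0266, gained). Camera's preset correlation added 8 list calls and fry 9, with none lost. Lists not called were rerun only for MAPK pathway activity score, G1/S, G2/M and p53 genes against DMSO. All added calls were therefore among those, so most of the misses described for them depend on the list test used.

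Of the values of named genes, 10 calls ended and 1 was gained with one library left out, and 4735 stayed on their side; those printed are named beside their values. Without the low-count filter 1 further call ended and 1 was gained, and calls were gained with library totals (1), with only the groups compared (2) and with the stricter filter (1). The cause was not tested. Depth limits genes near 0 counts in one group, where folds are bounds or carry wide counting intervals.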

Other observations

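Lists that were not called in any contrast are given here, each with 1 or 2 of its comparisons against DMSO. PRMT5 complex and arginine methyltransferase genes had 1 higher and 6 lower of 12 with belvarafenib (adjusted p 0.0814 with an estimated correlation, as for all lists here), and Sm, LSm and snRNP protein genes of the spliceosome 3 higher and 20 lower of 29 (0.25). RAS-RAF-MEK-ERK pathway components had 15 higher and 4 lower of 21 (0.258) and cholesterol biosynthesis genes 5 higher and 14 lower of 24 (0.919) in MRTX1719 with belvarafenib. Glycolysis and hypoxia genes had 12 higher and 4 lower of 23 (5 lower adjusted over the list alone; 0.206) with MRTX1719, and nuclear-encoded oxidative phosphorylation genes 25 higher and 6 lower of 42 (26 higher adjusted over the list alone; 0.754). Receptor tyrosine kinase genes had 10 higher and 2 lower of 23 (11 higher adjusted over the list alone; 0.203) with the adagrasib label, and lung lineage markers 3 higher and 3 lower of 11 (0.39) in MRTX1719 with adagrasib. Mitochondrially encoded transcripts were individually higher in 11 of 13 with MRTX1719 (median 0.51, adjusted p 0.666) and in 12 of 13 with adagrasib added (median 0.45, adjusted p 0.588). Germline and cancer-testis genes (4 tested, 1 lower with MRTX1719) and blood, endothelial and fibroblast markers (3 tested, 3 higher with MRTX1719) were too few for the list test.

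Lists called in some contrasts but not against DMSO included interferon-stimulated genes with belvarafenib (25 higher, 2 lower of 36, 26 higher adjusted over the list alone; adjusted p 0.259), ATF4 and amino acid response genes with belvarafenib (23 lower, 4 higher of 28, median -1.44; adjusted p 0.0995), cyclins, CDKs and CDK inhibitors with MRTX1719 (10 lower, 6 higher of 19; adjusted p 0.0637) and epithelial genes in MRTX1719 with belvarafenib (8 higher, 6 lower of 16; adjusted p 0.186). EGFR, a receptor tyrosine kinase gene, was at 865 ± 15.6 CPM in DMSO, 669 ± 30.9 in MRTX1719, 633 ± 23.1 with the adagrasib label and 367 ± 13.6 in belvarafenib.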
